A study of Mus musculus with 4 samples.

How the data were processed

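Total RNA (40 ng per sample) was amplified, labelled with biotin and hybridised to Affymetrix mouse gene arrays, 1 array per sample, per the labels' protocols. The table used here holds the deposited log2 values of the authors, 1 per probe set and array, and 4 arrays in 2 groups. How the authors corrected background, normalized and summarised the probes is not given in the sources used here, and neither are array batches or scan dates. Background correction could not be repeated from such values, so its effect was not tested. A floor on low values was tried, but it left the same 397 higher and 471 lower genes and so decides nothing about background.

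Of 34760 probe sets, 21640 named 1 gene in the platform annotation, 1321 named several and 11799 were unlisted there. No gene was named from a probe set with several genes, so some members of the lists were not analysed here. Of the 19938 genes, 19855 matched a current RefSeq entry of the GRCm38.p6 gene table, which was used for names. Each gene was represented by its probe set with the highest mean over the 4 arrays, and 953 genes had more than 1. Genes above the 30th percentile of the mean, a log2 value of 6.42, were tested, which left 13956. Non-neural genes had a median of 6.39, so values near that level carry little signal over background.

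Changes are olaparib minus DMSO on the log2 scale. They were tested with lmFit and eBayes (trend=TRUE) in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Every adjusted p in the text comes from limma. Replicate numbers name arrays only, and no pairing was used. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 23 lists with at least 5 tested members. They were tested again with an estimated correlation, where camera rests on only 2 residual degrees of freedom, and with fry. The comparison, the lists, the rule for named genes and most alternatives were set before the data were examined. The rule named 10 genes chosen for the biology, the 10 largest rises and 10 largest falls past the threshold with separated groups (without predicted genes and olfactory or vomeronasal receptors), and up to 4 members per list by smallest p. In all 868 genes past the threshold the groups were separated. Separation occurred in 47.1% of all genes tested, where chance gives 33.3%.

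The alternatives were no filter and a filter at the 50th percentile, quantile normalization, median centring, a floor at the 10th percentile, eBayes without trend, robust eBayes, array weights, the mean of a gene's probe sets, an adjusted p of 0.1, folds of 1.3 and 2, and leaving out each array. Leaving out an array leaves a group with 1 array, which is then assumed to vary like the other group. The median within-group SD was 0.048 for DMSO and 0.077 for olaparib. Without a DMSO array the spread came from the wider olaparib pair alone. A call lost there need not mean that the change depended on that DMSO array. Cyclic loess normalization and a fit over all 21704 probe sets above the same signal were added after seeing the data.

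The fit was tested on simulated data for this comparison, with 200 of 13956 genes changed in each of 20 simulations. It recovered 53.5% of genes changed by 1.3-fold, 95.6% at 1.5-fold and 100% at 2-fold, and 5.04% of its calls were false. The simulated spreads followed the prior that the fit assumes, so this test does not bear on the choice of rows that share the prior. Both simulated groups also had the same spread, unlike the real medians of 0.048 for DMSO and 0.077 for olaparib. The rates may therefore differ for the real arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.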

Results

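Transcript levels were measured in primary neurospheres from the subventricular zone of adult C57BL/6 mice, the region beside the lateral ventricles that holds neural stem and progenitor cells. The cells received control siRNAs and a virus carrying Pax6, a transcription factor that drives neuronal differentiation. They were then differentiated for 10 h by withdrawal of growth factors. One group of 2 arrays came from cells kept in 0.01% DMSO, and the other group of 2 arrays from cells kept in 100 nM olaparib, an inhibitor of the DNA repair enzymes PARP1 and PARP2, in the same solvent. The labels call the arrays of a group biological replicates. The median log2 value of an array lay between 6.60 and 6.68, and the small number of arrays limits the precision. Over the 13956 genes tested, Pearson's r across genes was 0.996 between the DMSO arrays and 0.993 between the olaparib arrays. Between the groups r ran from 0.986 to 0.988. Genes are not independent replicates, so these values carry no test.

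The comparison asked which transcripts differ when PARP activity is inhibited while the cells turn towards neurons. Of 36 p53 targets tested, 11 rose and 0 fell, and of 47 structural genes of immature neurons, 11 fell and 3 rose. Nrep, which encodes a protein of regenerating neurons, fell by 1.44 on the log2 scale (SE 0.13, adjusted p = 1.79e-06). Dcx, the microtubule-binding protein of migrating neuroblasts, fell by 1.05 (SE 0.10, adjusted p = 4.36e-06), from 9.12 ± 0.12 with DMSO to 8.07 ± 0.07 with olaparib (SD, n = 2 each). Gfap, the intermediate filament protein of astrocytes, fell by 1.03 (SE 0.13, adjusted p = 6.12e-05). Hmox1, the haem-degrading enzyme induced by oxidative stress, rose by 1.07 (SE 0.13, adjusted p = 2.49e-05), a 2.10-fold change.

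In limma, 397 genes were higher and 471 lower with olaparib at an adjusted p under 0.05, or 6.22% of the genes tested. Of these, 45 rose and 76 fell by at least 1.5-fold, and 1 rose and 8 fell by at least 2-fold. At an unadjusted p under 0.05 there were 2660 genes, where chance alone would give 698. These counts rest on how the spread of a gene is estimated from only 2 residual degrees of freedom, which limma supplements with a prior shared across rows. With 1 row per gene that prior was worth 18.1 degrees of freedom. When all 21704 probe sets above the same signal shared it, including the noisier ones with several genes or no listed gene, it was worth 5.25, its variance was also larger, and 1 gene was higher and 11 were lower. The genes past the threshold in both were Dcx, Nrep, Igfbp5, Mfsd2a, Pdp1, Fxyd6, Draxin, Rgr and Rtn4rl1, together with Tspan15, Sncaip and Thbs1, which were named after their values were seen. The log2 changes are the same in both fits. The error assigned to them differs, and so do the rows adjusted over, 13956 against 21704. Adjusted over the gene rows alone, 44 genes passed with all probe sets in the fit. Adjusted over all 21704, no gene named here besides those listed above passed, so neither Gfap nor Hmox1 did. With 1 array left out, the spread comes from the 2 arrays of the other group alone, so the following counts depend on which group that is. The median SD was 0.048 for DMSO and 0.077 for olaparib. Without DMSO replicate 1 the counts were 97 higher and 161 lower, and without DMSO replicate 2 they were 128 and 165. Without olaparib replicate 1 they were 1274 and 838, and without olaparib replicate 2 they were 566 and 1032.

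**Figure D1:**
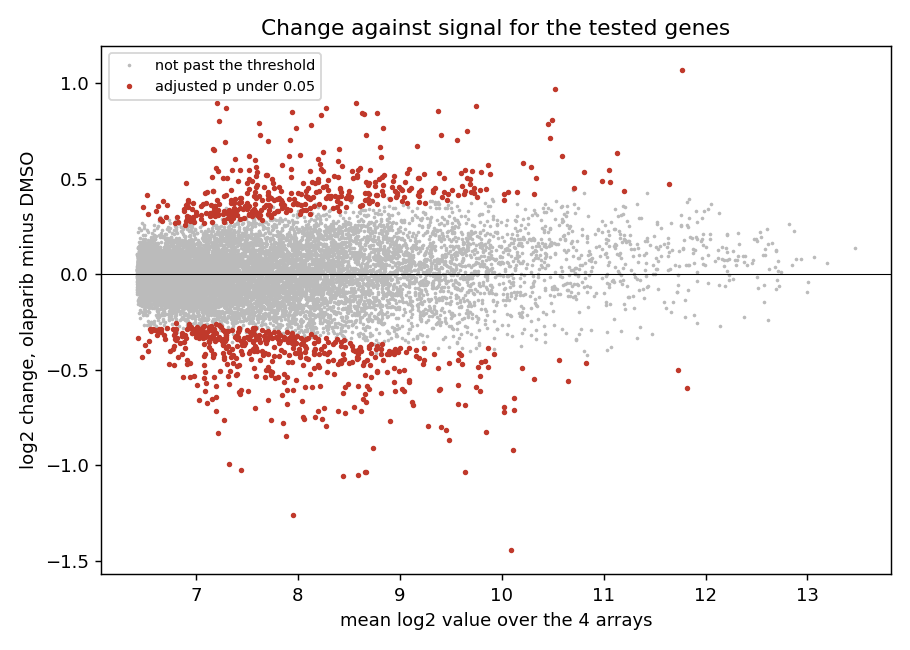
Each point is a gene, with its mean log2 value over the 4 arrays on the horizontal axis and its log2 change (olaparib minus DMSO) on the vertical axis. Red points mark the 397 higher and 471 lower genes at an adjusted p under 0.05, and grey points the other genes tested.

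Among the largest falls, Igfbp5, a secreted binding protein of insulin-like growth factors, fell by 1.26 on the log2 scale (SE 0.09). Mfsd2a, a lipid transporter, fell by 1.05, and Pdp1, a phosphatase that activates pyruvate dehydrogenase, by 1.04. Fxyd6, a regulator of the sodium pump, fell by 1.04, Draxin, an axon guidance protein, by 1.02, Rgr by 0.99 and Mmd2 by 0.92. Among the largest rises, the small RNAs Rny3 and Rny1 rose by 0.97 and 0.87. Ptgs2, the inducible cyclooxygenase, rose by 0.90 and Cbr3, a carbonyl reductase, by 0.90. Phlda3, a p53-induced inhibitor of AKT, rose by 0.88, Rtn4rl1 by 0.87, Dcxr by 0.86, Calcrl by 0.85 and Cend1 by 0.84. Their adjusted p lay at or below 0.000424. The dimmer group had a mean of 6.75 for Ptgs2, 6.83 for Rgr, 6.86 for Rny1, 6.93 for Draxin, 7.32 for Igfbp5 and 7.51 for Calcrl. These lie within the range of 31 genes of tissues unrelated to brain (75th percentile 6.63, highest 7.77), so the sizes of these changes are less certain. The dimmer group also lay under 7.77 in 40 of the 74 genes past the threshold that the rule named, and under 6.63 in 1. Among the 40 are Camk2a, Ccne2, Gad2, Myt1 and Celf3, named below, at 6.71 to 6.84.

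**Figure D2:**
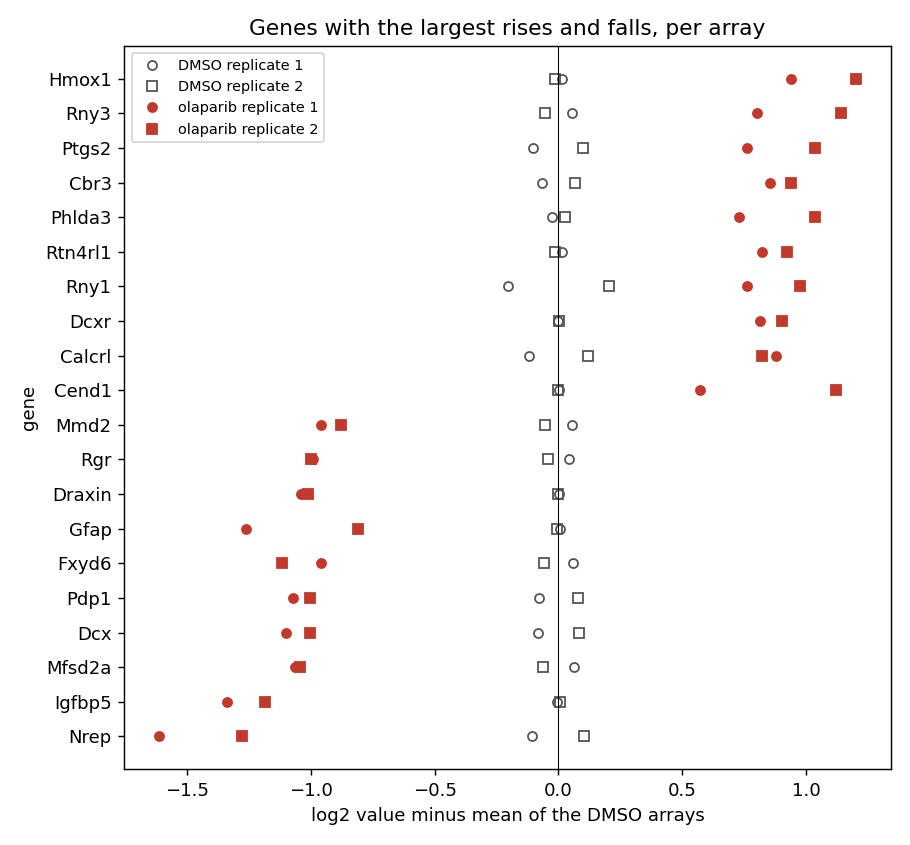
The log2 value of each array minus the mean of the DMSO arrays (horizontal axis) is shown for the 10 largest rises and 10 largest falls (vertical axis). Open symbols are DMSO arrays and filled symbols olaparib arrays, circles replicate 1 and squares replicate 2. Hmox1 lay highest at a mean change of 1.07 and Nrep lowest at -1.44.

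The genes fixed for reporting whatever their values included the drug's targets and neurogenic factors. Parp1 changed by -0.04 (SE 0.09, adjusted p = 0.913) and Parp2 by -0.10 (SE 0.09, adjusted p = 0.622). Pax6 differed by 0.06 (SE 0.11, adjusted p = 0.869). All arrays came from cells given a virus carrying Pax6, and viral and endogenous transcripts were not told apart. Pou3f4, a neurogenic factor, fell by 0.41 (SE 0.09, adjusted p = 0.00869), but did not pass without DMSO replicate 1 or without DMSO replicate 2 (adjusted p up to 0.190 over its 15 alternatives). Meis2, a cofactor of Pax6, differed by -0.40 (adjusted p = 0.0533, and between 0.000111 and 0.633 over its 15 alternatives, of which 7 put it past the threshold), Sox11 by -0.22 (adjusted p = 0.246) and Nfib by -0.10 (adjusted p = 0.765). Without olaparib replicate 1 the change of Meis2 was -0.26. Tubb3, a tubulin of neurons, differed by -0.32 (adjusted p = 0.134, and between 0.000395 and 0.768 over its 15 alternatives, of which 3 put it past the threshold). Its change was -0.15 without olaparib replicate 1 and -0.49 without olaparib replicate 2. Th differed by 0.01 (adjusted p = 0.978), at a mean of 6.49 with DMSO, close to the median of 6.39 over those 31 genes.

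Of 24 gene lists fixed before the data were examined, 23 had enough members to test with camera, and 13 passed an adjusted p of 0.05, 7 higher and 6 lower. That call used a preset correlation between genes of 0.01. With an estimated correlation 0 lists passed, 3 had an unadjusted p under 0.05, and the smallest adjusted p was 0.303. In that setting camera judges a list on only 2 residual degrees of freedom, so a list needs a far larger statistic to pass. A call lost there does not by itself count against the list. On simulated lists of 30 genes shifted by 0.15 on the log2 scale, camera called 20 of 20 with the preset correlation and 0 of 20 with an estimated one. The simulated genes were drawn independently, which favours the preset value. In the 13 lists the estimated correlation ran from -0.026 to 0.655, and it was highest for cholesterol synthesis at 0.655, growth factor feedback at 0.433, mitosis at 0.427 and stem cell and astrocyte genes at 0.395. For such lists the p with the preset value is too small if the estimate holds. A call could also be lost without a higher correlation, through the fewer degrees of freedom alone. For transcription factors of neuronal commitment the estimate was 0.010, at the preset, yet camera's unadjusted p went from 5.74e-08 to 0.0323. For immediate early genes the estimate was -0.026, and that p went from 9.13e-07 to 0.0296. The setting with an estimated correlation also missed all 20 simulated shifts, in genes drawn independently. The test fry called 0 of these 13 lists as moving one way. The 1 list it called was that of homologous recombination, which camera did not. It called 14 lists as changing in either direction, all of the 13 but the growth factor feedback list, together with the interferon and hypoxia lists. In 10 of the 13 lists the median moved by over 1.5 times when 1 array was left out, and those values stand with each list.

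Direct targets of p53, the transcription factor activated by DNA damage, were higher as a list, with a median change of 0.21 over 36 members (adjusted p = 7.20e-10; adjusted p = 0.318 with an estimated correlation). Of these, 11 rose, 0 fell and 25 did not pass, and 13 rose when adjusted over the list alone. Phlda3 rose by 0.88 and Pmaip1, a BH3-only inducer of apoptosis, by 0.60. The death receptor gene Tnfrsf10b rose by 0.51 and Gtse1 by 0.49. With all probe sets in the limma fit, none of the 36 passed. Adjusted p was then 0.0653 for Phlda3, 0.0576 for Pmaip1 and 0.0798 for Gtse1. Tnfrsf10b did not pass without DMSO replicate 1 (adjusted p up to 0.0840 over its 15 alternatives).

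Immediate early genes had a median change of 0.15 over 35 members (adjusted p = 4.63e-06; adjusted p = 0.303 with an estimated correlation), with 7 higher, 2 lower and 26 not past the threshold, or 12 and 3 adjusted over the list alone. Ier3 rose by 0.70 and Atf3 by 0.51, while the matricellular genes Ccn1 and Ccn2 fell by 0.91 and 0.78. NF-kB targets had a median of 0.20 over 23 members (adjusted p = 4.63e-06; adjusted p = 0.303 with an estimated correlation), with 6 higher, 0 lower and 17 not past the threshold, or 7 higher adjusted over the list alone. Their median was 0.13 without DMSO replicate 2 and 0.04 over 32 members without a filter on dim genes. They included Ptgs2 at 0.90 and the chemokine gene Ccl2 at 0.60. Feedback genes of growth factor signalling had a median of 0.18 over 25 members (adjusted p = 5.41e-05; adjusted p = 0.486 with an estimated correlation), with 7 higher, 0 lower and 18 not past the threshold, or 7 and 1 adjusted over the list alone. The median of this list was 0.06 without olaparib replicate 2, 0.32 without olaparib replicate 1 and 0.11 without DMSO replicate 2. Ccnd1, which encodes cyclin D1, rose by 0.62 and Fosl1 by 0.51. Ier3 belongs to all 3 of these lists. Targets of ATF4 and ER stress genes had a median of 0.10 over 36 members (adjusted p = 0.000313; adjusted p = 0.486 with an estimated correlation), with 7 higher, 1 lower and 28 not past the threshold, or 10 and 1 adjusted over the list alone. Their median was 0.15 without olaparib replicate 1. Mthfd2 rose by 0.55, Atf4 by 0.55 and Nupr1 by 0.54. Phgdh, an enzyme of serine synthesis named after its value was seen, fell by 0.34. Ccnd1, Atf4 and Phgdh did not pass when either DMSO array was left out, nor did Phgdh without a filter or under median centring, with adjusted p up to 0.213, 0.169 and 0.408 over the 15 alternatives of each.

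Cholesterol synthesis genes had a median of 0.18 over 25 members (adjusted p = 4.01e-07; adjusted p = 0.486 with an estimated correlation), with 7 higher, 0 lower and 18 not past the threshold, or 11 higher adjusted over the list alone. Their median was 0.30 without olaparib replicate 1. Fdps rose by 0.70 and Lss by 0.48. Idi1 rose by 0.75 on its brighter probe set and changed by 0.25 on the other. DNA replication genes had a median of 0.09 over 51 members (adjusted p = 0.000438; adjusted p = 0.486 with an estimated correlation), with 5 higher, 0 lower and 46 not past the threshold, and 5 higher adjusted over the list alone. Their median was 0.05 without olaparib replicate 2. Orc6 rose by 0.61 and Ccne2, which encodes a cyclin of S phase entry, by 0.35. Mitosis genes had a median of -0.13 over 44 members (adjusted p = 4.63e-06; adjusted p = 0.486 with an estimated correlation), with 0 higher, 7 lower and 37 not past the threshold, or 1 and 7 adjusted over the list alone. Their median was -0.08 without olaparib replicate 1. Ect2 fell by 0.43 and the mitotic kinase gene Plk1 by 0.40. Calls were lost without DMSO replicate 1 for Idi1, Lss and Plk1, without DMSO replicate 2 for Fdps and Orc6, and with either left out for Ccne2. Over the 15 alternatives of each, adjusted p reached 0.0671 for Idi1 and Fdps, 0.0877 for Lss, 0.126 for Plk1, 0.162 for Orc6 and 0.137 for Ccne2.

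Transcription factors of neuronal commitment had a median of -0.20 over 22 members (adjusted p = 4.40e-07; adjusted p = 0.303 with an estimated correlation), with 0 higher, 7 lower and 15 not past the threshold, or 9 lower adjusted over the list alone. Without a filter on dim genes the median was -0.09 over 34 members. Myt1 fell by 0.61, Prox1 by 0.58 and Nfia by 0.56. Structural genes of immature neurons had a median of -0.09 over 47 members (adjusted p = 0.00194; adjusted p = 0.486 with an estimated correlation), with 3 higher, 11 lower and 33 not past the threshold, or 6 and 16 adjusted over the list alone. Besides Dcx, Nsg2 fell by 0.74 and Celf3 by 0.51. The neurofilament gene Nefm rose by 0.69, and so did Gap43 by 0.57 and Robo1 by 0.51, which were named after their values were seen. Genes of olfactory bulb interneurons had a median of -0.10 over 20 members (adjusted p = 0.00132; adjusted p = 0.486 with an estimated correlation), with 0 higher, 3 lower and 17 not past the threshold, or 6 lower adjusted over the list alone. Their median was -0.0063 without DMSO replicate 1, -0.06 over 27 members without a filter and -0.19 with a filter at the 50th percentile. The guidance receptor gene Robo2 fell by 0.76, Gad2, a GABA-synthesizing enzyme, by 0.67, and Meis1 by 0.45. Synaptic genes had a median of -0.08 over 31 members (adjusted p = 0.00531; adjusted p = 0.486 with an estimated correlation), with 1 higher, 5 lower and 25 not past the threshold, or 2 and 8 adjusted over the list alone. Camk2a fell by 0.53 and Syt4 by 0.47, and Camk2b, named after its value was seen, rose by 0.42. Without olaparib replicate 1 the adjusted p was 0.125 for the immature neuron list and 0.106 for the synapse list, whose median was then -0.04. The synapse median was -0.03 without DMSO replicate 1, and without olaparib replicate 2 the medians were -0.15 for the immature neuron list and -0.13 for the synapse list. Among the genes named here, Prox1 did not pass without DMSO replicate 1, Syt4 without DMSO replicate 2, and Nfia, Gap43, Robo1, Meis1 and Camk2b when either DMSO array was left out. Over the 15 alternatives of each, adjusted p reached 0.112 for Prox1, 0.134 for Syt4, 0.226 for Nfia, 0.199 for Gap43, 0.241 for Robo1, 0.202 for Meis1 and 0.351 for Camk2b.

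Neural stem cell and astrocyte genes had a median of -0.10 over 38 members (adjusted p = 8.04e-05; adjusted p = 0.489 with an estimated correlation). Of these, 1 rose, 9 fell and 28 did not pass, or 1 and 14 adjusted over the list alone. The median was -0.03 without olaparib replicate 1 and -0.19 without olaparib replicate 2, and -0.15 under cyclic loess normalization. Besides Gfap, the water channel gene Aqp4 fell by 0.71, Id3 by 0.65 and Ednrb by 0.60. The member that rose was the cystine transporter gene Slc7a11 at 0.53, named after its value was seen, which the ATF4 list also holds. Ednrb, Id3 and Slc7a11 did not pass when either DMSO array was left out, with adjusted p up to 0.205, 0.0843 and 0.323 over the 15 alternatives of each.

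**Figure D3:**
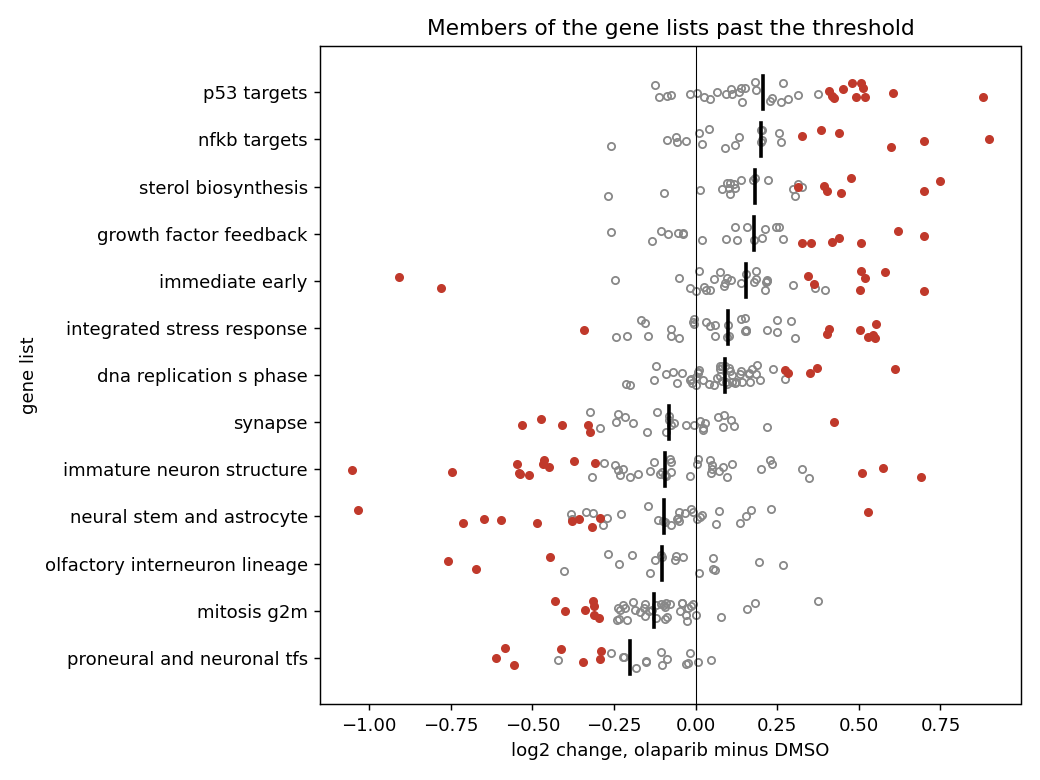
Each point is a gene of a list past the threshold, with its log2 change (olaparib minus DMSO) on the horizontal axis and the lists on the vertical axis. Red points are at an adjusted p under 0.05, open points are not, and black bars mark list medians, from 0.21 for p53 targets to -0.20 for transcription factors of neuronal commitment.

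The other 10 lists did not pass with camera, and the medians of some of them changed sign when 1 array was left out. The PARP and base excision repair list had a median of -0.03 and a mean of 0.01 over 37 members (adjusted p = 0.888), and homologous recombination genes a median of 0.02 over 34 members (adjusted p = 0.251). With fry the homologous recombination list was called as higher (adjusted p = 0.0348). Neither held a gene past the threshold in limma, with 3 and 5 at an unadjusted p under 0.05. Over all 13956 genes tested 2660 were at that p. Of 11 histone genes (median 0.06, mean -0.0042, adjusted p = 0.888) 0 passed, with 1 at an unadjusted p under 0.05. Oligodendrocyte lineage genes had a median of 0.06 over 25 members (adjusted p = 0.294), and Cspg4 rose by 0.33 while Lhfpl3 fell by 0.46. Ependymal genes had a median of -0.06 over 17 members (adjusted p = 0.180), microglial genes of -0.03 over 9, vascular and fibroblast genes of -0.01 over 11 and genes of unrelated tissues of -0.02 over 14 (adjusted p = 0.888 in each of the last 3). Interferon response genes had a median of 0.01 over 34 members (adjusted p = 0.294), although 6 of them rose, among them Ifit3 by 0.45 and Bst2 by 0.41. Hypoxia and glycolysis genes had a median of -0.01 and a mean of 0.03 over 29 members (adjusted p = 0.607). Vegfa rose by 0.39 and Slc2a1 fell by 0.39. Hk1 rose by 0.48 on its brighter probe set and changed by -0.01 on the other. Its change was 0.28 without DMSO replicate 1, and 0.23 as the mean of its probe sets. Of the genes named here, Lhfpl3 did not pass without DMSO replicate 1, Vegfa without DMSO replicate 2, and Cspg4, Ifit3, Bst2, Slc2a1 and Hk1 when either DMSO array was left out. Slc2a1 and Hk1 also did not pass without a filter or under median centring, nor did Hk1 as the mean of its probe sets. Over the 15 alternatives of each, adjusted p reached 0.158 for Lhfpl3, 0.396 for Vegfa, 0.186 for Cspg4, 0.687 for Ifit3, 0.343 for Bst2, 0.705 for Slc2a1 and 0.908 for Hk1. The mitochondrial list had only 2 members and was not tested.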

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

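The test of this probe set was chosen after the data were seen. Outside the genes compared above, probe sets with several genes or no listed gene were tested in a limma fit with all other probe sets. Of the 756 with several genes, 0 passed, with 102 at an unadjusted p under 0.05. Of the 5774 without a listed gene, 1 passed, with 852 at an unadjusted p under 0.05. That 1 probe set fell by 1.45 on the log2 scale (adjusted p = 0.0224), from 8.17 and 8.19 with DMSO to 6.87 and 6.60 with olaparib. Tested within their own class, 0 of either kind passed, with 70 and 474 at an unadjusted p under 0.05.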

How the results depend on the processing

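Cyclic loess normalization, the fit over all probe sets and the exchange of its prior were chosen after seeing the data. With all probe sets in the fit, 1 gene was higher and 11 lower. Adjusting the same p-values over the gene rows alone gave 44 genes. Over those rows, 123 passed with only the prior degrees of freedom lowered from 18.1 to 5.25, and 625 with only the prior variance exchanged. Robust eBayes in that fit gave 102. Without a filter 257 genes were higher, cyclic loess gave 719 lower, and an adjusted p of 0.1 gave 606 higher and 715 lower. Leaving out 1 array gave from 97 to 1274 higher and from 161 to 1032 lower. Among named genes, 29 calls were lost without DMSO replicate 1, 26 without DMSO replicate 2, 0 without olaparib replicate 1 and 3 without olaparib replicate 2, and 65 with all probe sets in the fit. Gained calls numbered 8 without olaparib replicate 1, 11 without olaparib replicate 2, and 4 each under quantile normalization and cyclic loess. The count at an unadjusted p under 0.05 and a fold of at least 1.5 was 121, and 121 with all probe sets. It was 9 at a fold of 2 and 548 at 1.3, and from 134 to 151 with 1 array left out. The number of lists past the threshold was 0 with an estimated correlation and 1 with fry, from 11 to 13 with 1 array left out, and 13 under every other alternative. With an estimated correlation camera rests on only 2 residual degrees of freedom, so its count of 0 decides little. The mean correlation between groups, 0.987, was 0.990 without a filter and 0.982 with a filter at the 50th percentile. That follows from the dim genes each adds or removes. Of 74 named genes past the threshold, 9 passed under each of the 15 alternatives run for single genes, and no list median past the threshold reversed. Sizes moved more: without a filter the medians were 0.04 for NF-kB targets, -0.09 for transcription factors of neuronal commitment and -0.06 for olfactory interneuron genes, which was -0.19 with a filter at the 50th percentile, and cyclic loess gave -0.15 for the stem cell and astrocyte list. Causes not stated here were not tested. Values near 6.39, the median level of non-neural genes, limit what can be seen for genes such as Th. In 40 of the 74 the dimmer group lay under 7.77, the highest level of a non-neural gene. In 1 of the 74 it lay under 6.63, the 75th percentile of those genes. No paired analysis was possible because the labels give no number that ties an array of one group to an array of the other.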

Other observations

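A further 4 groups were targets of NRF2, of YAP and SRF and of BMP signalling, and genes of the hedgehog pathway. Their lists were drawn up after the data were seen and hold genes already known to have changed. Only values are therefore given and no list test. Of 17 targets of NRF2, the regulator of antioxidant genes, 5 rose and 1 fell. Hmox1 rose by 1.07, Cbr3 by 0.90 and Gclm by 0.51, and Abcc4 fell by 0.46. Of 12 targets of YAP and SRF, 1 rose and 4 fell. Ccn1 fell by 0.91, Ccn2 by 0.78, Myl9 by 0.75 and Thbs1 by 0.71, and F3 rose by 0.37. Of 8 hedgehog genes 0 rose and 2 fell, the receptor gene Ptch1 by 0.67 and Boc by 0.28. Gli1 changed by -0.05 (adjusted p = 0.831), at a mean of 6.74 with DMSO. Of 13 BMP targets 0 rose and 3 fell, Id3 by 0.65, Bmper by 0.58 and Id4 by 0.36. Members outside the fixed rule were named after their values were seen. Gclm, F3, Boc, Id3 and Id4 did not pass when either DMSO array was left out, nor Boc without olaparib replicate 2, nor Ptch1 without DMSO replicate 1. F3 and Boc also did not pass without a filter, F3 and Id4 under median centring, and Boc with eBayes without trend. Over the 15 alternatives of each, adjusted p reached 0.346 for Gclm, 0.607 for F3, 0.303 for Boc, 0.0843 for Id3, 0.309 for Id4 and 0.0798 for Ptch1.

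Ribosome biogenesis genes, listed before their values were seen, had a median of 0.12 over 34 members, and 3 of them rose. Camera's adjusted p over 6 further lists, which include those drawn up after the data were seen, was 0.000518. It was 0.356 with an estimated correlation. Unadjusted, these camera p were 0.000259 and 0.308. The 53 ribosomal protein genes had a median of 0.10, and 0 passed in limma. Of them 3 were at an unadjusted p under 0.05, against 2660 of all 13956 genes tested.

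The tests of shared members, of the neuronal median under cyclic loess, of astroglial genes, of small RNAs and of other splits were chosen after the results were seen. For the rise of p53 targets, the list's median was 0.21 before cyclic loess normalization and 0.18 after it. That normalization lowered the median change of the brightest eighth of genes from 0.05 to 0.0055. It moved a gene by a median of 0.010 and at most by 0.129, so these values held little signal-dependent shift to remove. A scaling or signal-dependent shift between arrays as large as the list's rise is thereby argued against, while smaller shifts are not. Whether members shared with the immediate early and ATF4 lists account for the rise was not decided by leaving them out. Only 2 of the 36 are shared, the other 34 had a median of 0.21, and no 2 members could have brought it below 0.18. A second list of p53 targets, drawn up before its values were seen, had a median of 0.16 over 26 members, with 7 higher and 1 lower (adjusted p = 0.000167; adjusted p = 0.145 with an estimated correlation). This is consistent with a wider p53 response as a hypothesis, while a batch that follows the treatment stays open.

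For the fall of neuronal genes, a scaling shift as large as the fall is argued against in the same way. Cyclic loess moves had a 95th percentile of 0.046. The 120 distinct members of the 4 neuronal lists had a median of -0.10 both before and after it. That 25 of their 26 lower calls stayed decides nothing, as 851 of all 868 calls did. Another 4 members rose, Nefm by 0.69, Gap43 by 0.57, Robo1 by 0.51 and Camk2b by 0.42. A lower share of neurons with every other cell type unchanged would leave astroglial genes level or slightly higher, but 9 members of the stem cell and astrocyte list fell. A lower share of neurons together with a change in astroglial cells may still apply, and so may a change in transcription within the cells.

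Of 43 small non-coding RNA genes, 6 rose and 6 fell. A difference in the recovery of small RNAs that moved them all one way would put most of them on one side, but the commoner direction held 50% of the 12. A loss that depends on the kind of small RNA was not tested.

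The 4 arrays can be split into 2 and 2 in only 3 ways, too few for a share under 0.05. The real split, 1 of the 3, gave 868 genes and the highest other split 0 in limma, with 541 and 76 genes at an unadjusted p under 0.05 in the other splits.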
